A study of Rattus norvegicus with 13 samples.

How the data were processed

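Gene expression was measured in the frontal cortex of male Sprague-Dawley rats 1 month after head trauma or sham surgery. Each of 13 samples had its own 1-colour Agilent rat array. Per the file headers, the authors scanned the arrays and extracted the spots with Agilent Feature Extraction 10.5.1.1, and the deposited scanner files give each spot's signal as an intensity. The processed signal in these files is a background-subtracted and spatially detrended intensity that Feature Extraction had not scaled between arrays, with low values replaced by surrogates. The authors also deposited a table of normalised log2 values. Its 13 columns share a median of 8.15 and nearly the same sorted values (largest SD of a sorted value over arrays 0.004), so the deposited log2 table is quantile-normalised. Each of its 13 columns correlated best with the scanner values of its own array.

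The labels gave 4 groups: rotational injury (3 arrays) with its own sham group (3 arrays), and lateral fluid percussion injury (3 arrays) with its own sham group (4 arrays). The replicates are labelled as separate samples, so each p-value measures the spread between these samples. All arrays of a model lay on 1 slide. On each slide the trauma arrays and the sham arrays lay in different columns. The order was opposite on the 2 slides. An additive column effect of equal size on both slides therefore cancels in the mean of both models and enters the difference in full. Rows were not balanced in this way. Rotational sham lay in rows 2 to 4 and rotational trauma in rows 1 to 3. Percussion trauma lay in rows 1, 2 and 4 and percussion sham in rows 1 to 4, so a row effect need not cancel in the mean.

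Each array held 62976 spots, of which 4259 were control spots. The 58717 other spots were used, and spots marked as outliers were set missing. Spots of 1 probe were averaged on the log2 scale, which gave 30367 probes. The log2 processed signal was scaled by subtracting each array's upper quartile. A probe was kept if it was well above background on every array of at least 1 group, which left 20004 probes. For a gene with several probes the probe of highest mean was used, which gave 17231 genes. Of these, 6 had a missing value, and 4577 carry only an accession, a probe name or a provisional name. No probe was saturated (0 on any array). Probe names were updated from a gene table of the GRCr8 assembly, used for names only: 18379 probes matched by accession, 2474 by symbol and 540 by synonym, and 8974 kept the name in the file. Of all probes, 4163 received a symbol other than the one in the file. Probe coordinates are those of the array files, on rn4.

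The statistics used R 4.3.3 with limma 3.58.1, and Python 3.11.15 drew the figures. A linear model with a mean per group was fitted to all 13 arrays (9 residual degrees of freedom, 2.22 prior degrees of freedom). It gave 4 two-sided contrasts: rotational trauma minus its sham, percussion trauma minus its sham, the mean of both, and the difference of both. The p-values were adjusted by the Benjamini-Hochberg method over all genes at a threshold of 0.05. Effects are log2 differences with the moderated standard error (SE). Where no array of a group was above background, the fold change is given as a bound against the lowest signal above background, and left out if no bound above 0 could be given.

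There were 36 gene lists, each with at least 5 measured genes: reactive astrocyte, general astrocyte, general microglia, phagocytic microglia, antigen presentation, interferon response, complement, cytokines and chemokines, myelin, oligodendrocyte precursor, synaptic vesicle, glutamate signalling, GABA receptors and transport, interneuron, immediate early, monoamine receptors, ion channels, axon and cytoskeleton injury, neurotrophic, endothelial barrier, mural cell, meninges and matrix, choroid plexus and ependyma, red blood cell, T cell, neutrophil and monocyte, striatum, upper cortical layers, deep cortical layers, oxidative stress and metallothionein, heat shock and unfolded protein, autophagy and lysosome, apoptosis and p53, oxidative phosphorylation, circadian clock, and glucocorticoid response. They were tested with limma's camera with a preset correlation of 0.01, adjusted over the 36 lists of a comparison. Camera with an estimated correlation and limma's fry were run beside it. Camera compares a list with all other genes, and fry tests whether a list's genes move, on balance, in 1 direction. The score of a list on an array is the mean of its genes' centred log2 values. Scores were compared by a two-sided exact permutation test within slides (700 relabellings for both models together, with a smallest possible p of 0.00143).

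Genes are named by a fixed rule. For each comparison it took up to 12 passing genes per direction whose groups do not overlap. If fewer passed, it added the genes of smallest unadjusted p up to 8 per direction, as values that did not pass. For the difference it took 5 per direction. It further took up to 4 members per list that passed over the list alone, and a fixed set of anchor genes. Genes without a symbol were left out, with 1 exception that is stated in place. F13a1, Drd4, Rcvrn, Stk32a, Galns and Zzef1 met the rule in some comparisons, but their differences are left out there since no array of some compared groups was above background. The anchor genes Clec7a, Il1b and Ccl2 were not measured above background. The comparisons, the lists, the naming rule and most alternatives were fixed before the data were examined.

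The fit was tested on simulated data with the same groups, 17225 genes and 200 changed genes. For the rotational comparison, 76% of 2-fold and 93% of 4-fold changes were recovered, with 5 unchanged genes called. For the percussion comparison, 79% of 2-fold and 96% of 4-fold changes were recovered, with 10 unchanged genes called. For the mean of both, 86% of 2-fold and 99% of 4-fold changes were recovered, with 9 unchanged genes called. A list shifted by 0.5 was called in each of these comparisons, with 0 other lists. The simulated genes varied independently of each other, and slides and models did not differ. The simulation therefore does not show how many lists are called falsely when genes are correlated.

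The alternatives were other background corrections and scalings, the deposited log2 table, other filters on dim probes, other choices among a gene's probes, separate fits per model, array weights, other variance models and thresholds, the array row as a factor, a replicate block, and leaving out each array in turn. The number of arrays limits the precision of every value.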

Results

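The series measured transcripts in the frontal cortex of male rats 1 month after 2 kinds of experimental head trauma. Rotational injury is a rapid angular acceleration of the head, and was studied in 3 trauma and 3 sham samples. Lateral fluid percussion injury is a pressure pulse delivered to the dura through an opening in the skull, and was studied in 3 trauma and 4 sham samples. Sham animals received anaesthesia and surgery without trauma. On the 13 arrays, between 67.0% and 74.1% of the spots were well above background, and 17231 genes were tested. This share followed the slide column. It was 72.7% to 74.1% in column 1 (rotational sham and percussion trauma) and 67.0% to 72.5% in column 2 (rotational trauma and percussion sham). The arrays of a group correlated at r between 0.988 and 0.997 across genes, where genes are not independent replicates.

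The 2 sham groups were not alike. Arc, an activity-regulated gene of neurons, was 3.36 higher on the log2 scale in percussion sham than in rotational sham, and Selenoi, which encodes an enzyme of phospholipid synthesis, was 2.56 higher. By limma, 4087 genes differed between the sham groups at an adjusted p under 0.05, 1700 of them higher and 2387 lower in percussion sham. Arc and Selenoi were chosen after their values were seen. Each model had its own slide, so model and slide cannot be told apart, and trauma was compared only with the sham of its own model.

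The first comparison asked what differed in the cortex 1 month after rotational injury. Ccng1, which encodes cyclin G1 and is a target gene of p53, fell 5.03-fold. Its scaled log2 signal was 0.84 ± 0.60 (SD, n = 3) in sham and −1.49 ± 0.06 (SD, n = 3) in trauma, lower in 3 of 3 trauma samples than in any sham sample (log2 difference −2.33, SE 0.28, adjusted p = 0.0383). The Ccng1 probe lies on chromosome 10 from 25778638 to 25778912. The transcript ENSRNOT00000049083, which the files give no symbol for and which was chosen after its value was seen, rose at least 7.20-fold (adjusted p = 0.0383). It was not above background on any sham array (0 of 3) and lies on chromosome X from 140696248 to 140696307. At the level of gene groups, camera with a preset correlation called meningeal and extracellular matrix, myelin, interferon and reactive astrocyte genes higher, and genes typical of the striatum lower. None of these calls held with an estimated correlation (smallest adjusted p 0.254), and 0 members of these lists passed over all genes.

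These were the genes that passed for rotational trauma in limma, 2 of 17231, with 1183 genes at an unadjusted p under 0.05 where 862 are expected by chance (491 higher, 692 lower). The genes of smallest p that did not pass included Cebpd, a transcription factor of the acute-phase response, with a log2 difference of 0.72 (SE 0.10, adjusted p = 0.0746). They also included the mitochondrial assembly factor gene Ndufaf6 with 0.83 (adjusted p = 0.0615). Hes1, a transcriptional repressor downstream of Notch, differed by −2.16 (SE 0.32, adjusted p = 0.102), and the serine protease gene Klk8 by −1.50 (adjusted p = 0.16). Ogn, which encodes the matrix proteoglycan osteoglycin, differed by 2.07 (SE 0.34, adjusted p = 0.141). Hpn, which encodes the membrane protease hepsin, was at least 13.9-fold higher (adjusted p = 0.154). Its scaled log2 signal was −3.15, −2.46 and −3.09 in the rotational trauma samples. Percussion sham 1, a sample without trauma, had a similar value of −2.99, while percussion sham 2 to 4 had −7.40, −6.32 and −6.70. Further values that did not pass were Slc15a2 0.72, Pank1 0.57, Ctrl 0.83, Atp7a 1.21, Smim26 −0.61, Or8c19 −0.50 and Sec23b −0.49. Stk32a and Galns were also among the smallest p and did not pass, but no trauma array was above background for them and no bound could be given.

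Among the gene lists, that of meninges and matrix had the lowest p after rotational trauma. All 16 measured members were higher, with a median log2 difference of 0.94 (camera adjusted p = 4.39e-15). Of these members 0 passed over all genes and 8 passed when adjusted over the list alone, among them Ogn, Aldh1a2 with 1.42, Col1a2 with 1.23 and Ptgds with 0.98. Its score was higher in 3 of 3 trauma samples than in any sham sample. The reactive astrocyte list had 12 of 15 members higher (median 0.45, camera adjusted p = 2.25e-05), led by Steap4 with 1.23 and the copper-binding ferroxidase gene Cp with 1.01. Its scores were unequal, at 0.496, −0.188 and 0.202 in trauma samples 1 to 3 against −0.191, −0.220 and −0.225 in sham samples 1 to 3. The classical astrocyte marker Gfap differed by −0.36 and did not pass (adjusted p = 0.93), while the intermediate filament gene Vim differed by 0.84 (adjusted p = 0.613). The myelin list had 17 of 19 members higher (median 0.34, camera adjusted p = 1.39e-09), and the interferon response list 18 of 20 (median 0.26, camera adjusted p = 1.84e-07). On the scores of these 2 lists, 2 of 3 trauma samples lay above every sham sample, and for interferon response the third lay below every sham sample (exact permutation p = 0.4 for each). The myelin median was 0.11 without rotational sham 2, and the interferon response median 0.07 without rotational trauma 1. The glucocorticoid response list had 10 of 12 members higher (median 0.20, camera adjusted p = 3.4e-06), and 3 members passed when adjusted over the list alone: Errfi1 with 0.54, Sgk1 with 0.82 and Sult1a1 with 0.93. None of these calls held with an estimated correlation, where adjusted p = 0.254 for meninges and matrix, reactive astrocyte and glucocorticoid response, and adjusted p = 0.282 for myelin and interferon response.

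The striatum list, markers of the tissue below the frontal cortex, had 11 of 11 members lower (median −0.46, camera adjusted p = 0.000253, adjusted p = 0.355 with an estimated correlation). This call was lost without rotational sham 1, where the median was −0.23. The dopamine receptor gene Drd1 differed by −0.70 (adjusted p = 0.881), and 0 trauma samples lay below every sham sample on this list's score. Lists of neuronal transmission were slightly lower: glutamate signalling in 19 of 22 members (median −0.12), GABA receptors and transport in 13 of 17 (median −0.11) and synaptic vesicle in 18 of 19 (median −0.10). Their camera adjusted p was 0.0229, 0.034 and 0.034, and with an estimated correlation adjusted p = 0.292, 0.282 and 0.544, and each call was lost without rotational sham 2 or without rotational trauma 3. In contrast with its list, Slc17a6, which encodes a vesicular glutamate transporter, differed by 0.88 and passed when adjusted over the list alone. The other lists above 0 that passed for rotational trauma were mural cell (0.25, camera adjusted p = 7.68e-05), complement (0.15, 0.000314), phagocytic microglia (0.16, 0.000314), oxidative stress and metallothionein (0.16, 0.000314), neutrophil and monocyte (0.29, 0.000674) and choroid plexus and ependyma (0.50, 0.0229). For complement and for neutrophil and monocyte 1 of 3 trauma samples lay below every sham sample on the list's score, the phagocytic microglia call was lost without rotational trauma 1, and the choroid plexus and ependyma call was lost without rotational sham 2 or without rotational trauma 3. These had adjusted p with an estimated correlation of 0.265 for mural cell, 0.31 for neutrophil and monocyte, and 0.254 for the others. Further members that passed when adjusted over their list alone were Serping1 (0.74), Stat2 (0.31), Vtn (0.90), Cd163 (1.17), Gjb6 (0.49), Ccn2 (0.67), Nfkbia (0.73) and Il1a (at least 1.32-fold lower). In all, 15 of 36 lists passed, 11 higher and 4 lower, and 0 passed with an estimated correlation or with fry.

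With 3 samples against 3, an exact permutation test cannot go below p = 0.1, so each list's score alone could not pass. The count of 2 genes fell to 0 without rotational sham 2, rotational sham 3, percussion trauma 2, percussion sham 2 or percussion sham 4 and to 1 without percussion sham 1, and was 5 without percussion trauma 3, 6 without rotational trauma 1, 7 without percussion trauma 1 and 12 without rotational trauma 3.

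**Figure D1:**
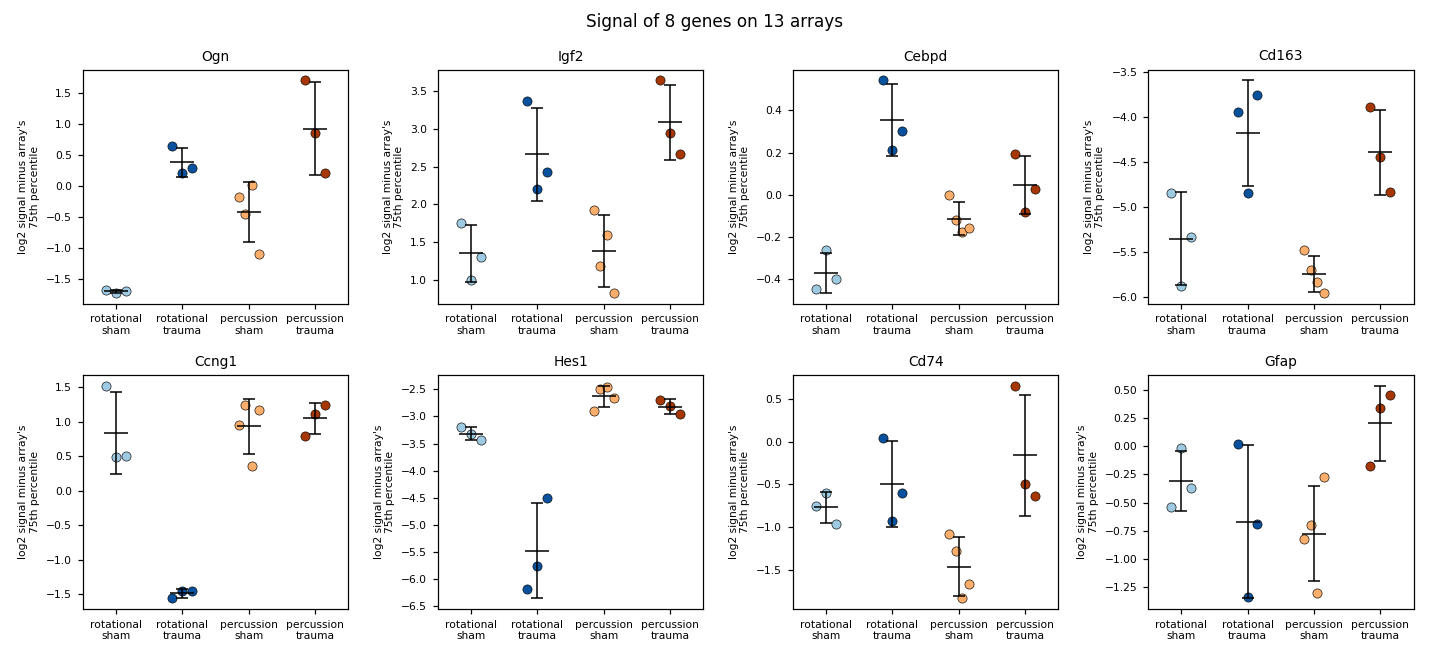
Scaled log2 signal (log2 signal minus the array's upper quartile) of 8 genes, 1 point per array, with the mean and SD of each group. Ccng1 is lower in rotational trauma (−1.49 ± 0.06) than in rotational sham (0.84 ± 0.60) while percussion trauma (1.05 ± 0.23) lies by its sham (0.93 ± 0.40), and Ogn and Igf2 are higher in the trauma group of both models.

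The second comparison asked what differed 1 month after lateral fluid percussion. Camera with a preset correlation called genes of the meninges and matrix, reactive astrocytes, complement and antigen presentation higher as groups, and immediate early genes of neuronal activity lower. None of these calls held with an estimated correlation (smallest adjusted p 0.434) or with fry. Gfap, the astrocyte intermediate filament gene, was −0.77 ± 0.42 (SD, n = 4) in sham and 0.20 ± 0.34 (SD, n = 3) in trauma, a log2 difference of 0.98 that did not pass over all genes (SE 0.31, adjusted p = 0.303). Cd74, the invariant chain of class II antigen presentation, differed by 1.30 (SE 0.32, adjusted p = 0.228), and Arc by −1.08 (SE 0.23, adjusted p = 0.199). Col1a1, a fibrillar collagen chain, differed by 1.81 (SE 0.39, adjusted p = 0.215).

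For percussion trauma limma called 0 genes (smallest adjusted p 0.154), with 1948 at an unadjusted p under 0.05 (1298 higher, 650 lower). The genes of smallest p that were higher were Nup188 (0.62), Fut4 (0.66), Clec4a3 (0.73), the cholesterol exporter gene Abca1 (0.67), Apoa5 (0.61), Hes5 (0.59), Plekha2 (0.73) and Klhl18 (at least 1.28-fold). Those that were lower were Yipf3 (−0.32), Coro1a (−0.38), Pla2g2c (−0.48), Arc, Trim45 (−0.59), Cstf3 (−0.43), Pipox (−0.80) and Rpl3l (−0.62). Igf2, a growth factor gene strongly expressed in the meninges and choroid plexus, differed by 1.70 (SE 0.34, adjusted p = 0.199) and lies on chromosome 1 from 202906641 to 202906700.

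The meninges and matrix list again had 16 of 16 members higher, with a median of 1.14 (camera adjusted p = 2.46e-12). Of its members 0 passed over all genes and 14 passed when adjusted over the list alone, among them Col1a1, Ogn with 1.34, Fmod with 1.34 and Fn1 with 0.82. All 15 reactive astrocyte members were higher (median 0.58, camera adjusted p = 2.07e-06), and 8 passed when adjusted over the list alone, among them Gfap, Vim with 1.07, Serping1 with 1.00, Cp with 1.14 and Aspg with 1.17. All 13 complement members were higher (median 0.58, camera adjusted p = 9.85e-06), with C1s at 0.85, C1r at 0.77 and C4a at 0.82 passing when adjusted over the list alone. In antigen presentation 15 of 16 members were higher (median 0.35, camera adjusted p = 0.000124), and the 3 that passed when adjusted over the list alone were the class II genes Cd74, RT1-Da with 1.27 and RT1-Bb with 1.44. These lists had adjusted p = 0.434 with an estimated correlation, or adjusted p = 0.554 for antigen presentation. For each of these 4 lists, the scores of 3 of 3 trauma samples lay above every sham sample. The exact permutation p was 0.0286 for each, the smallest that 3 against 4 can give, and was not adjusted over the lists. The 4 lists were picked for their camera call in the same comparison, so this p decides nothing further. The phagocytic microglia, mural cell and neurotrophic lists had the same exact permutation p, and camera did not call the neurotrophic list.

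All 15 immediate early members were lower (median −0.29, camera adjusted p = 9.85e-06, adjusted p = 0.48 with an estimated correlation), with Arc and the phosphatase gene Dusp1 (−0.67) passing when adjusted over the list alone. Fos differed by −0.70 (adjusted p = 0.512), and 2 of 3 trauma samples lay below every sham sample on the list's score. Phagocytic microglia had 13 of 14 members higher (median 0.20, camera adjusted p = 0.000514), with Lgals3 at 1.20 and Gpnmb at 0.67. The general microglia genes Aif1 (−0.05) and C1qb (0.04) did not pass. Mural cell had 10 of 12 members higher (median 0.44, camera adjusted p = 0.00362), with Acta2 at 0.55, Pdgfrb at 0.45, Vtn at 0.64 and Myh11 at 0.51, and cytokines and chemokines 13 of 15 (median 0.27, camera adjusted p = 0.00653), with Tnfrsf1a at 0.66. Red blood cell had 8 of 8 lower (median −0.29, camera adjusted p = 0.0371), a call that held in 18 of 26 settings and was lost without percussion trauma 1, percussion sham 2 or percussion sham 4. The mural cell call was lost without percussion trauma 1. With an estimated correlation these had adjusted p = 0.434, 0.574, 0.558 and 0.655 in that order. Further members that passed when adjusted over their list alone were Cxcl13 (at least 1.75-fold higher), Ccl3 (at least 1.44-fold higher), Cd163 (at least 2.46-fold higher), Aqp1 (1.74), Kcnj13 (1.27), Sult1a1 (0.73), Irf1 (0.31), Klf9 (−0.32), Cort (−0.61), Npy (−0.28) and Shank3 (−0.24, while another probe of Shank3 gave 0.18).

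In all, 9 of 36 lists passed for percussion trauma, 7 higher and 2 lower, and 0 passed with an estimated correlation or with fry. The count of 0 genes became 1 without percussion trauma 3 or percussion sham 1, 2 without rotational trauma 2 and 5 without percussion trauma 2.

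**Figure D2:**
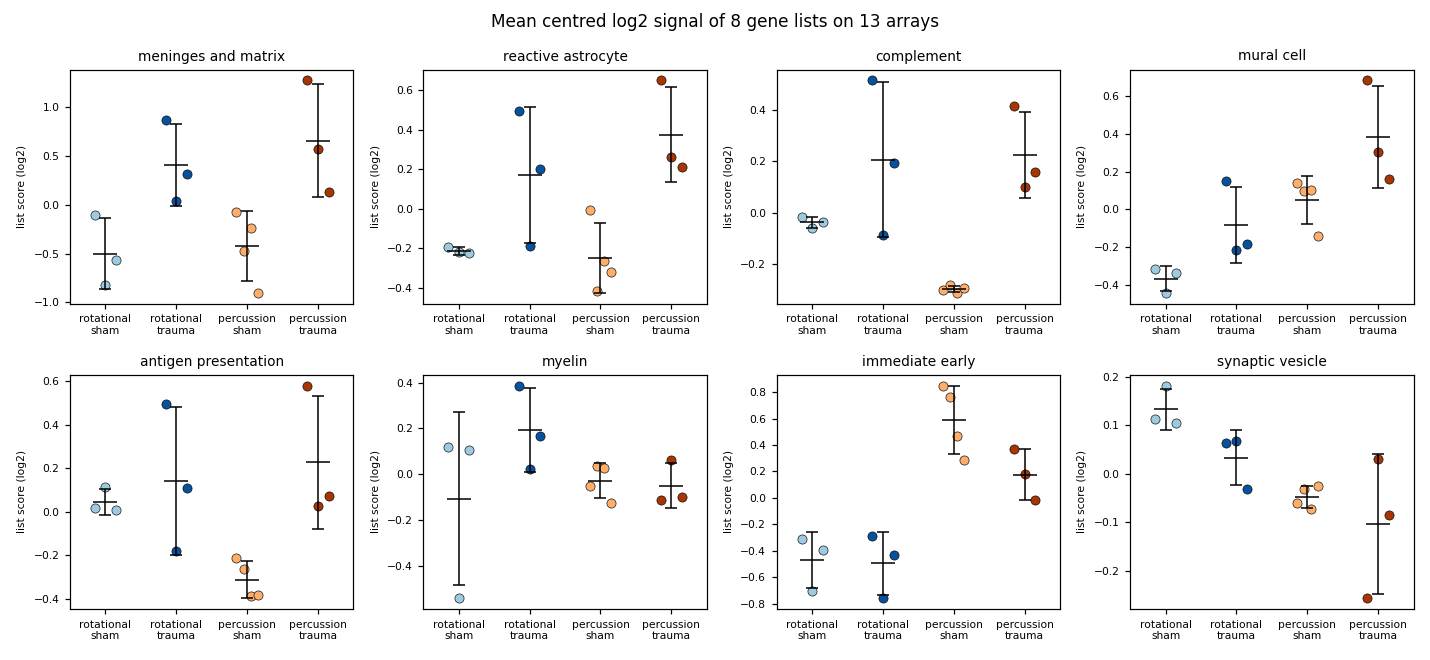
Score of 8 gene lists (mean centred log2 signal of the list's genes), 1 point per array, with the mean and SD of each group. The meninges and matrix score is higher in all trauma samples than in the sham samples of their model, with means of −0.50 and 0.41 in rotational sham and trauma and of −0.42 and 0.66 in percussion sham and trauma.

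The third comparison asked what the 2 models shared, as the mean of both trauma effects. Camera with a preset correlation called meningeal and matrix genes higher, by about 2-fold, and reactive astrocyte, complement, phagocytic microglia and vascular mural cell genes higher by smaller amounts. These calls did not hold with an estimated correlation (smallest adjusted p 0.118, and 0.237 for mural cell). Ogn had a mean log2 difference of 1.71 (SE 0.23), Igf2 of 1.51 (SE 0.25), and both were higher in every trauma sample than in any sham sample of the same model. Cp differed by 1.07 (SE 0.19), and none of these 3 genes passed over all genes (adjusted p = 0.186 for each). Cd163, a scavenger receptor gene of macrophages at the brain's borders, differed by 1.17 after rotational trauma and was at least 2.46-fold higher after percussion trauma, where no sham array was above background.

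For the mean, limma called 0 genes (smallest adjusted p 0.186), with 1538 at an unadjusted p under 0.05 (879 higher, 659 lower). The named genes of smallest p also included Cebpd with 0.44, Rab27a with 0.43, the macrophage lectin gene Clec10a with 1.17 and Fam180a with 0.89. On the lower side they were Ccng1 with −1.11, Hes1 with −1.18, Klk8 with −0.89, Rpl3l with −0.49, Cstf3 with −0.31, Trim45 with −0.42 and Gnat1 with −0.19. For Ccng1, Hes1, Klk8 and Cebpd the groups overlapped in percussion. The percussion difference was 0.12 for Ccng1, −0.19 for Hes1 and −0.28 for Klk8. For Rab27a, Trim45 and Cstf3 the trauma and sham groups overlapped in the rotational model.

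The list of meninges and matrix had 16 of 16 members higher for the mean of both (median 1.07, camera adjusted p = 2.01e-22), and 15 passed when adjusted over the list alone against 0 over all genes. Reactive astrocyte had 15 of 15 higher (median 0.35, camera adjusted p = 7.81e-10, 6 passing when adjusted over the list alone), complement 12 of 13 (median 0.36, camera adjusted p = 4.14e-08, 5 passing) and phagocytic microglia 13 of 14 (median 0.20, camera adjusted p = 9.68e-07, 4 passing). Examples were Vim with 0.96, Serping1 with 0.87, C4a with 0.64, Cfd with 0.96, Lgals3 with 0.92 and Ch25h with 0.60. The anchor gene C3 of the complement list overlapped between trauma and sham samples in both models. Its scaled log2 signal was 0.08, −1.06 and −0.69 after rotational trauma, against −0.85, 0.68 and −0.04 in sham. After percussion trauma it was −0.35, 0.56 and 0.70, against −1.20, −0.57, −0.57 and 0.24 in sham. The anchor gene Cst7 of the phagocytic microglia list also overlapped in both models. With an estimated correlation adjusted p = 0.118 for each of these 4 lists, which were also the 4 that passed with fry (adjusted p = 0.0352). Mural cell had 10 of 12 higher (median 0.36, camera adjusted p = 2.69e-06, adjusted p = 0.237 with an estimated correlation), with Vtn at 0.77 and Tagln at 0.60. In the exact permutation test of list scores, chosen after the data were seen, 5 lists passed and all were higher: meninges and matrix, reactive astrocyte and mural cell (p = 0.00143, the smallest possible, adjusted p = 0.0171), oxidative stress and metallothionein (adjusted p = 0.0257) and complement (adjusted p = 0.0411). Phagocytic microglia did not (exact permutation p = 0.01, adjusted p = 0.06). In the oxidative stress list, Slc7a11, the cystine transporter gene, differed by 0.41 and Txnip by 0.71.

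The reactive astrocyte, complement and phagocytic microglia scores moved with the meninges and matrix score within groups. Their slopes on it were 0.41 ± 0.11, 0.25 ± 0.10 and 0.24 ± 0.09 (SE). Their mean trauma effects were 0.50 ± 0.12, 0.38 ± 0.09 and 0.31 ± 0.09 (SE), and at equal meninges and matrix score 0.10 ± 0.14, 0.13 ± 0.12 and 0.06 ± 0.12. The mural cell score had a slope of 0.39 ± 0.05 and a mean trauma effect of 0.31 ± 0.10 before and −0.08 ± 0.06 at equal score. For antigen presentation these values were 0.37 ± 0.13, 0.32 ± 0.12 and −0.05 ± 0.16, and for oxidative stress and metallothionein 0.08 ± 0.04, 0.12 ± 0.03 and 0.04 ± 0.05. In each model every trauma sample had a higher meninges and matrix score than every sham sample. The values at equal score thus extend the slope within groups over scores that trauma and sham samples do not share.

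The other lists above 0 that passed for the mean were interferon response (median 0.20, camera adjusted p = 3.22e-06), antigen presentation (0.24, 1.4e-05), neutrophil and monocyte (0.22, 0.000335), myelin (0.12, 0.000465), cytokines and chemokines (0.25, 0.00345), T cell (0.16, 0.0161), oxidative stress and metallothionein (0.09, 0.0161) and glucocorticoid response (0.09, 0.0424). Those below 0 were striatum (−0.30, 0.000465), immediate early (−0.22, 0.0019), synaptic vesicle (−0.09, 0.00626), red blood cell (−0.28, 0.00716), GABA receptors and transport (−0.05, 0.0309) and ion channels (−0.06, 0.0309). The adjusted p of these lists with an estimated correlation was 0.308 for oxidative stress and metallothionein, 0.344 for ion channels, 0.403 for glucocorticoid response, 0.409 for myelin and 0.337 for the others. For every list that passed, the median, the mean and the test had the same sign. Not all of these calls were shared by both models. The score difference was 0.30 after rotational and −0.02 after percussion trauma for myelin, and 0.29 and −0.04 for glucocorticoid response. In the same order it was −0.03 and −0.41 for immediate early, and 0.02 and 0.37 for cytokines and chemokines. It was 0.10 and 0.54 for antigen presentation, and −0.55 and −0.09 for striatum. The other lists of this paragraph had the same sign in both models. In all 19 of 36 lists passed, 13 higher and 6 lower, and 0 with an estimated correlation.

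Several of these calls for the mean rested on single arrays. The glucocorticoid response call held in 13 of 25 settings, ion channels in 16, GABA receptors and transport in 17 and T cell in 18 of 24, each lost on leaving out any of at least 2 single arrays. The myelin call was lost without rotational sham 2, whose myelin score was −0.54 against 0.12 and 0.11 in the other rotational shams, and the immediate early call without rotational trauma 2 or without percussion trauma 3. The red blood cell call was lost without rotational trauma 2 or percussion trauma 1, synaptic vesicle without percussion trauma 1, and oxidative stress and metallothionein without percussion trauma 3.

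The lists called in both models numbered 5, all higher in both: meninges and matrix, reactive astrocyte, complement, phagocytic microglia and mural cell. With an estimated correlation none of them held in either model (smallest adjusted p 0.254 for rotational and 0.434 for percussion trauma). The count of 0 genes for the mean became 95 with array weights, 28 with a replicate block and 21 without rotational trauma 2, and was 6 without rotational trauma 3, 2 without percussion trauma 3 and 1 without rotational sham 1, percussion trauma 1 or percussion sham 3.

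Across the 17231 genes the 2 trauma effects had Pearson's r = 0.188 and Spearman's rho = 0.0375, and 49.5% of genes had the same sign; genes are not independent replicates. Among genes with an unadjusted p under 0.05 in both models, 138 were higher in both where 37.0 are expected of independent lists. Another 27 were lower in both (26.1 expected), and 111 went in opposite directions (70.6 expected). Without rotational trauma 1, r was 0.0777.

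**Figure D3:**
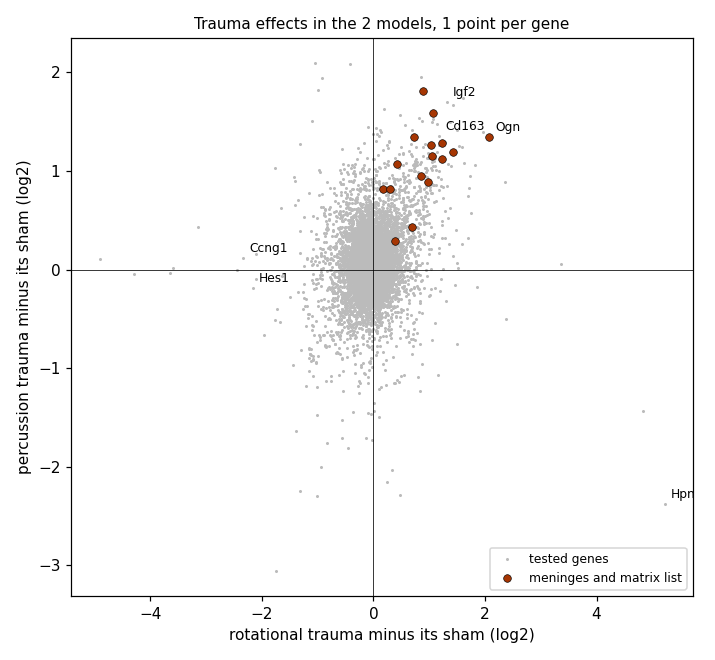
Log2 difference of percussion trauma and its sham (vertical axis) against that of rotational trauma and its sham (horizontal axis), 1 point per gene, with the 16 meninges and matrix genes marked. All 16 lie above 0 on both axes, while r over all genes is 0.188.

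The fourth comparison asked where the 2 models differed, as the rotational effect minus the percussion effect. Camera with a preset correlation called myelin, glucocorticoid response and immediate early genes higher after rotational than after percussion trauma, each relative to its sham. These 3 calls did not hold with an estimated correlation (adjusted p = 0.961, 0.791 and 0.961 in that order), and fry called 0 lists. In the myelin list 17 of 19 members had a positive difference (median 0.38, camera adjusted p = 1.22e-05), with Mog at 0.41 after rotational and −0.25 after percussion trauma. Much of this rested on rotational sham 2, without which the median was 0.15; Mog was −0.42 in that array and 0.36 in each of the other rotational shams. In the glucocorticoid response list 10 of 12 did (median 0.22, camera adjusted p = 7.78e-05), and 4 passed when adjusted over the list alone: Sgk1 with 1.01, Klf9 with 0.47, Errfi1 with 0.59 and Tsc22d3 with 0.65. In the immediate early list 12 of 15 did (median 0.22, camera adjusted p = 0.00113), with Arc at 1.58 and Dusp1 at 1.29.

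For the difference limma called 0 genes (smallest adjusted p 0.0652), with 1476 at an unadjusted p under 0.05 (343 higher, 1133 lower). Among named genes above background in every group the smallest adjusted p belonged to Hes5, a Notch target gene, with −1.08 (SE 0.15, adjusted p = 0.0652). Further values that did not pass were Ccng1 with −2.45 (adjusted p = 0.148), Ndufaf6 with 0.89, Pank1 with 0.69, Ctrl with 1.15 and Ddit4 with 1.31. Galns (adjusted p = 0.0652), Zzef1 and Drd4 were also among the smallest p, but no percussion sham array was above background for them and their differences are left out. In the exact permutation test of list scores 0 lists passed for the difference (smallest adjusted p 0.231). An effect of the slide column enters this difference in full, and the immediate early call was lost without rotational trauma 1 or without percussion trauma 3. The count of 0 genes became 8 without rotational trauma 3, 7 without rotational trauma 1, 2 without rotational sham 1 or percussion trauma 1, and 1 without percussion sham 1 or percussion sham 3.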

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

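In this part the correlation of both trauma effects over the genes above background was a planned test, and the tests on dim probes, on genes that rose from background and on the named genes lower after rotational trauma were chosen after the result was seen.

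On each slide trauma and sham arrays lay in separate columns, in opposite order on the 2 slides. A column effect shared by both slides would push the trauma effects of the 2 models in opposite directions. Against such a shared effect as the cause of the large rotational falls stands the median percussion effect of Ccng1, Hes1, Klk8 and Stk32a, −0.0362 (median SE 0.255). A shared column effect of equal size would give a rise as large as the fall. Stk32a was above background neither in rotational trauma nor in percussion, while Ccng1 (0.12), Hes1 (−0.19) and Klk8 (−0.28) were above background in percussion. A column effect on the rotational slide alone would leave percussion unchanged, so this test cannot speak to it. With dim probes kept, r between the models was −0.465 and 2982 genes passed for percussion trauma against 0 for the mean of both, so a column effect may be the source of those calls. Over the genes above background r was 0.188, over the bound of 0.1 set for its absence by less than the spread of 0.0992 between other splits, so for the genes as a whole the column and the kind of trauma cannot be told apart. The same holds for the 3 genes not above background in rotational sham and over 4-fold higher in rotational trauma, among them ENSRNOT00000049083 and Hpn: 66.7% had a lower value after percussion trauma, but 3 genes are too few for an exact binomial test and almost no percussion array was above background for them, so this decides nothing and a different response to the 2 kinds of trauma stays open and untested.

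Camera with a preset correlation called the trauma effect on 3 gene lists different between the models, and the slide column enters this test in full. With an estimated correlation the adjusted p was 0.961 for myelin, 0.791 for glucocorticoid response and 0.961 for immediate early genes, and the exact permutation of list scores called 0 lists for the difference. The median log2 difference, rotational minus percussion, was 0.383 for myelin genes, and 0.148 without rotational sham 2. It was 0.218 for glucocorticoid response genes. It was 0.224 for immediate early genes.

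In the percussion sham group, the only one with 4 samples, 12 of 167 values tested had 1 sample far from the others, and chance gives about 5%. The values are not independent of each other, and many of the 12 may be due to chance. The figures that follow are the gap to the nearest other sample as a share of the group's range. Percussion sham 1 stood apart on principal component 1 (0.856), which held 40.8% of the variance. Percussion sham 2 stood apart for the GABA receptor and transport score (0.931) and Abca1 (0.884). The distance can be small: the GABA receptor and transport scores of percussion sham lay between −0.031 and 0.005. Those of percussion trauma lay between −0.115 and 0.060. Percussion sham 3 stood apart for the glutamate signalling score (0.859), the striatum score (0.865) and Mog (0.851). Its gaps for ENSRNOT00000049083 (0.897) and Rcvrn (0.893) lie among values below background and do not show a sample apart. Percussion sham 4 stood apart for the mural cell score (0.844), Nfkbia (0.870), Stat2 (0.848) and Irf7 (0.957).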

How the results depend on the processing

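The settings without rotational trauma 1 and percussion sham 1 together, and the exact permutation of list scores, were chosen after the result was seen; the others were planned. No result past its threshold turned to the opposite direction past its threshold under any setting run, and no scaling moved the median of all genes by more than 0.1. For named genes 7257 values stayed on their side of the threshold, 171 moved past it and 27 fell short of it. Only Ccng1 and ENSRNOT00000049083 passed with the main settings, so all 27 belong to these 2 genes. Most of the values that stayed are of genes that did not pass in the first place. For lists these counts were 3661, 100 and 191. Where the values below differ from the main ones, the cause was not tested. The main counts of genes were 2 for rotational trauma and 0 for percussion trauma, for the mean and for the difference, and the main counts of lists were 15, 9, 19 and 3.

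Rotational genes numbered 4 with normexp background correction, 0 with quantile normalisation, 4 from the deposited table, 6 with the arrays of the rotational model only, 5 with trended and robust variance, and 4 at an adjusted p under 0.10. Array weights gave 58 rotational genes, 95 for the mean and 5 lists for the difference. Trended and robust variance gave 1 gene for the difference, and the threshold of 0.10 gave 4. With no filter on dim probes, 356 rotational, 2982 percussion and 3781 difference genes passed, r was −0.465, and 14 percussion lists and 0 difference lists passed; signal over background limits what these dim probes can show. With the array row as a factor there were 0 rotational and 4 percussion genes, 5 for the mean, and 5 lists for the difference.

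With a replicate block, which treats equal replicate numbers as paired, there were 0 rotational genes and 28 for the mean. Samples of equal number in a model correlated, after removal of group means, at 0.109, 0.265 and 0.0204 for rotational and 0.282, −0.0232 and −0.00579 for percussion, so the numbers were not taken as pairs. Without rotational trauma 1 and percussion sham 1 there were 10 rotational, 1 percussion and 13 difference genes, r was 0.0667, and 8 rotational lists passed. With an estimated correlation 0 lists passed in each of the 4 comparisons. With fry 0 passed for rotational trauma, percussion trauma and the difference, and 4 for the mean. The exact permutation of scores, which sets aside the other genes, passed 5 lists for the mean and 0 for the difference.

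Leaving out each array in turn, rotational genes ranged from 0 (without rotational sham 2, among others) to 12 (without rotational trauma 3), percussion genes from 0 to 5 (without percussion trauma 2), genes for the mean from 0 to 21 (without rotational trauma 2) and genes for the difference from 0 to 8 (without rotational trauma 3). The r of both effects ranged from 0.0777 (without rotational trauma 1) to 0.277 (without rotational trauma 2). Lists ranged from 12 to 21 for rotational trauma, from 7 to 12 for percussion trauma, from 14 to 21 for the mean and from 2 (without percussion trauma 3) to 6 (without rotational trauma 2) for the difference. Ccng1 and ENSRNOT00000049083 each lost the call in most of the fits that left out 1 array. For Ccng1 the adjusted p was 0.0525 without percussion sham 1, 0.156 with a replicate block and 0.177 with the arrays of the rotational model only. ENSRNOT00000049083 had an adjusted p of 0.152 with a replicate block, and differed by 1.44 with normexp background correction (adjusted p = 0.27). Neither of them passed without rotational trauma 1 or without rotational trauma 2, where other genes did. Without rotational sham 2 the immediate early list passed for the difference while its median was −0.02, and it did not pass without rotational trauma 1, without percussion trauma 3, with no filter on dim probes, or without rotational trauma 1 and percussion sham 1.

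The meninges and matrix, glucocorticoid response, interferon response and myelin lists passed for rotational trauma in all 26 settings with a preset correlation. For percussion trauma the meninges and matrix, reactive astrocyte, complement, antigen presentation, phagocytic microglia and immediate early lists did so. The glutamate signalling, GABA receptor and transport and synaptic vesicle lists passed for rotational trauma in 19, 17 and 16 of the 26 settings. The rotational complement and phagocytic microglia lists each passed in 24 and did not without rotational trauma 1 and percussion sham 1; the phagocytic microglia list also did not without rotational trauma 1 alone, and its lowest median was 0.03. The rotational choroid plexus and ependyma list passed in 20, not without rotational sham 2 or without rotational trauma 3, among others, with a lowest median of 0.06. The striatum list did not pass without rotational sham 1, and the percussion mural cell list did not without percussion trauma 1.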

Other observations

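In this part the camera tests of lists for the mean, the adjustment over a list alone and the other settings were planned. The pick of settings to set side by side, the exact permutation tests, all values at equal meninges and matrix score and the splits were chosen after the result was seen.

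Among genes typical of the choroid plexus, Aqp1, a water channel gene, had a mean log2 difference of 1.67 (SE 0.38, adjusted p = 0.186) and Kcnj13, a potassium channel gene, of 1.22 (adjusted p = 0.2), and both passed when adjusted over the list alone but not over all genes. The choroid plexus and ependyma list as a whole did not pass for the mean of both (4 of 6 members higher, median 0.63, camera adjusted p = 0.0735). The lysozyme gene Lyz2 differed by 0.36 (adjusted p = 0.265) and passed when adjusted over the neutrophil and monocyte list alone. In other settings, 122 genes passed for the mean in at least 1 of 4 settings (array weights, replicate block, without rotational trauma 2, array row as a factor) and 4 in at least 3 of them: Ogn, Cd163, Clec10a and Timp1.

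The remaining lists did not pass for the mean of both. Their medians were −0.08 for glutamate signalling, −0.07 for interneuron, −0.05 for axon and cytoskeleton injury, −0.04 for upper cortical layers, −0.02 for oxidative phosphorylation and for circadian clock, −0.01 for heat shock and unfolded protein, autophagy and lysosome, and apoptosis and p53, and 0.00 for monoamine receptors. They were 0.01 for neurotrophic, 0.02 for oligodendrocyte precursor, 0.03 for general astrocyte, 0.05 for general microglia, 0.09 for endothelial barrier and 0.11 for deep cortical layers. The test's direction was opposite to the median's for autophagy and lysosome, monoamine receptors and neurotrophic genes. The anchor genes of neurons, Snap25 (−0.25), Syp (−0.09), Slc17a7 (−0.04), Grin1 (−0.02), Pvalb (−0.19) and Sst (−0.13), did not pass, nor did the growth-associated gene Gap43 (−0.07) or the clock genes Per2 (−0.01) and Dbp (0.01).

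Camera with a preset correlation called the meninges and matrix, reactive astrocyte, complement, phagocytic microglia and mural cell lists higher after trauma in both models. None of these calls held in either model with an estimated correlation (smallest adjusted p 0.254 for rotational and 0.434 for percussion trauma). For complement, 1 rotational trauma sample lay below every sham sample on the list's score. The largest exact permutation p over the 5 lists was 0.01, which decides nothing since they were picked for being higher in both. Adjusted over all 36 lists, the largest exact permutation p of meninges and matrix, reactive astrocyte, complement and mural cell was 0.0411. This argues against a slide column effect of equal size on both slides, which cancels in the mean of both. For phagocytic microglia (0.06) column and trauma cannot be told apart. A row effect need not cancel, and in each group the array of lowest row had the highest meninges and matrix score. With the array row as a factor, that list still passed for the mean in camera at the preset correlation. A lower share of neurons would raise the markers of every other cell type alike. The meninges and matrix score differed by more than the general astrocyte, general microglia, myelin and endothelial scores, by 0.86 to 0.97 (largest exact permutation p = 0.00429). This test was run for that list only, which was picked for its rise, so it does not decide the question. The other lists were not tested in this way. More meningeal and vessel tissue in the trauma samples may account for part. At equal meninges and matrix score the mean effect was 0.0988 ± 0.137 (SE) for reactive astrocyte, 0.131 ± 0.122 for complement and 0.0617 ± 0.115 for phagocytic microglia. Trauma and sham samples of a model share no range of that score, so these values extend the slope within groups and cannot decide this. Of the 16 marker genes of the meninges and matrix list, 15 were above background on all sham arrays and 0 are held by another list. Whether such tissue was carried along at dissection or grew in response to the injury stays open, as does a response of the cortex that rises together with it.

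At equal meninges and matrix score the immediate early list was −0.66 ± 0.13 (SE) for the mean of both, against −0.22 ± 0.13 before. Of the 18 other lists that had passed for the mean by camera at the preset correlation, 2 still did, immediate early and striatum, both lower. All values at equal score in this paragraph extend the slope within groups over scores that trauma and sham samples do not share. Before this adjustment both had adjusted p = 0.337 with an estimated correlation, which was not run after it. For rotational trauma 3 of 14 other lists still passed (glucocorticoid response and interferon response higher, striatum lower), for percussion trauma 1 of 8 (immediate early, lower), and for the difference all 3. Lists newly called were immediate early (lower) for rotational trauma, myelin and striatum (both lower) for percussion trauma, and interferon response and oxidative stress and metallothionein (both higher) for the difference.

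Other splits of the same arrays within slides were counted, the real one included. For rotational trauma there are only 10 splits, too few for a share under 0.05; the real split gave 2 genes against at most 1 in another split (1 split as large, the real one), 1183 genes at an unadjusted p under 0.05 against at most 1560 (2 splits) and 15 lists against at most 20 (3 splits). For percussion trauma, with 35 splits, chance was not excluded: 1948 genes at an unadjusted p under 0.05 against at most 2918 (6 splits as large) and 9 lists against at most 11 (4 splits). The count of 0 genes against at most 8 decides nothing, since every split gives at least 0. For the mean, with 100 splits drawn at random from 700, chance was not excluded either: 1538 genes at an unadjusted p under 0.05 against at most 1917 (6 splits) and 19 lists against at most 22 (9 splits). Its count of 0 genes against at most 2 decides nothing for the same reason. For the difference, with the same 100 splits, it was not excluded: 1476 genes at an unadjusted p under 0.05 against at most 2357 (10 splits) and 3 lists against at most 20 (84 splits). The count of 0 genes against at most 6 again decides nothing. Lists at several times the real count in another split point to a structure of the samples other than trauma, or to a list test that calls too many at the preset correlation. These were not told apart by any test.

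For r of both trauma effects across genes, 3 of 100 splits, a random draw from 700, gave a value as high as 0.188 (highest other 0.210). This share is under 0.05, but it was not adjusted over the other split tests and Spearman's rho was 0.0375, so chance is not excluded. The value of r also rests on 1 array: without rotational trauma 1, r was 0.0777, within the SD of 0.0992 between the other splits.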
